A study of Mus musculus with 6 samples.

How the data were processed

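Whole retinas of mice at postnatal day 7 were profiled by RNA sequencing in 6 libraries, 3 labelled wild type (WT) and 3 labelled CTGF_KO. The labels describe the second group as deficient in connective tissue growth factor through an inducible Cre/lox system, on a C57BL/6 background. Per the labels' protocols, retinas were dissected and frozen, RNA was extracted with Trizol, polyadenylated RNA was selected, and strand-specific libraries were made with a dUTP kit and read from both ends on an Illumina HiSeq system. The series calls the replicates triplicates, and nothing in the labels says that each library came from a separate animal. So the p-values of single genes and transcripts measure the spread between these libraries, which may be partly technical.

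Per the submitters' processing notes, read quality was examined with FastQC, adapters were removed with cutadapt, reads were aligned to GRCm38 with HISAT2, and transcripts were assembled and quantified with StringTie. The series' design text adds that FPKM values and differential expression came from Ballgown. Tool versions are not given in the sources used here. The authors deposited the values as FPKM per gene and per transcript, which relate reads to the length of the feature and to the total of each library. The full tables list 13072 genes and 26721 transcripts, all protein coding, and 1 line in each was empty. The lowest value of the higher group mean was 0.5 FPKM in both tables, which shows that the authors removed features below that level. Reads assigned to other assembled or noncoding transcripts are not analysed here.

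Per the file headers, the deposited tables also give group means, a log2 fold change, a fold change, a p-value and a q-value. The 2 deposited group means are means of log2(FPKM + 1), although their headers say FPKM. The deposited log2 fold change equalled the difference of mean log2(FPKM + 1) to within 5.8e-15 for genes. The deposited p-value equalled that of a linear model per gene without moderation and without a library covariate, to within 3.67e-11. These deposited p-values and q-values were used only to describe the authors' own lists.

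The tables hold no read counts, so the sequencing depth of each library is unknown and no counting interval or detection floor is given. A value of exactly 0 in such a table can be a failed estimate, so a feature is described as listed at 0 and no fold is given against it. Because FPKM are not counts, the main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with trend on log2(FPKM + 1), which is the scale that Ballgown tests. Features with a mean of at least 0.5 FPKM over the 6 libraries were tested, which kept 12915 genes and 25082 transcripts. Adjusted p-values are Benjamini-Hochberg values over the features tested, with a threshold of 0.05. Every log2 difference is CTGF_KO minus WT on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. A looser count took an unadjusted p under 0.05 with at least a 1.5-fold difference on that scale. Errors beside log2 differences are standard errors (SE), and errors beside FPKM are standard deviations (SD) with n = 3.

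Before the data were examined, 34 lists of genes were fixed: pathways related to growth factor and matrix signalling, markers of retinal cell types, and markers of tissues that could be carried along or of RNA quality. The targeted gene itself was left out of every list. The 33 lists with at least 3 tested members were tested with camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. With that preset the genes of a list count as nearly independent, so camera p-values do not measure how far list levels vary between libraries. The estimated correlations were 0.759 for the cell cycle list, 0.453 for rods and 0.916 for lens. Camera was first run without a variance trend and then with one, to match the gene test, after its output had been seen. Each list was also tested with an estimated correlation and with fry. The level of a list in a library is the mean over its genes of log2(FPKM + 1), minus the mean of the WT libraries. These levels were also compared between the groups by a two-sided exact permutation of the libraries.

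The genes named in the text follow a rule fixed at the same time: Ctgf and its measured relatives; up to 12 genes per direction past the threshold with a mean of at least 1 FPKM and groups that do not overlap, filled up by the smallest unadjusted p; the 3 members with the smallest p of each list; the most abundant member of each cell type list; and the transcripts of Ctgf with 5 transcripts per direction chosen likewise. Of these the text names a part. Other transcripts of the genes so named were chosen after their values were seen. The result of 1 transcript that passed the threshold is not reported here. Coordinates are those of the deposited tables, on GRCm38. Exon numbers and lengths come from GENCODE M21 on the same build, in which 11481 of the 13072 genes and 25417 of the 26721 transcripts had the same versioned identifier and position. In M21 the targeted gene is called Ccn2.

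The gene and transcript tests were tried on simulated data with 200 changed features each. With the spread of the gene table, 14.9% of the genes changed by 0.5 on the log2 scale were recovered, 76.1% of those changed by 1 and 100% of those changed by 2, and 5.93% of all calls were false. For transcripts the recovered shares were 0%, 0% and 53%, and 7.89% of calls were false. Of 200 simulated lists without a change, 7 had a camera p under 0.05. The simulated errors were drawn independently for each gene and transcript. So these false rates hold for independent features and not for these libraries, where the genes of a list can vary together.

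Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter and a filter at 1 FPKM, rescaling to an equal FPKM total, upper-quartile scaling and quantile normalization, other variance models, library weights, the replicate number as a block, leaving out each library in turn, an adjusted p threshold of 0.1, and other list tests. A fit with the lens level as covariate and a fit without WT replicate 1 and CTGF_KO replicate 3 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.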

Results

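The libraries compare retinas labelled as deficient in connective tissue growth factor, a secreted matricellular protein encoded by Ctgf (also named Ccn2), with WT retinas at postnatal day 7, when the retinal vessels are still growing. The gene FPKM of a library summed to 208436 to 216436 in WT and 217674 to 230474 in CTGF_KO, so these totals did not overlap between the groups. In a single library 13 to 36 of the 13072 genes were listed at 0. Pearson correlations of log2(FPKM + 1) across genes were 0.970 to 0.984 within groups and 0.960 to 0.987 between groups, so the groups were not set apart by overall similarity. At the transcript level CTGF_KO replicate 2 stood apart, with 1875 transcripts listed at 0 against 716 to 861 in the other libraries.

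Ctgf (ENSMUSG00000019997.11, chromosome 10, 24595442 to 24598683, plus strand) was weakly expressed in both groups. Its FPKM was 0.932, 0.777 and 1.51 in WT replicates 1 to 3, and 0.587, 1 and 0.526 in CTGF_KO replicates 1 to 3. The means were 1.07 ± 0.387 and 0.704 ± 0.258 FPKM (SD, n = 3), and the log2 difference of −0.28 (SE 0.17) did not pass the limma test (adjusted p = 0.571). Its 1 listed transcript (ENSMUST00000020171.11) has 5 exons and gave −0.30 (SE 0.22, adjusted p = 0.819). The labels do not say which part of the gene was deleted, and reads from the remaining exons would still count, so Ctgf does not check the labels here. Cyr61, the only other measured member of the CCN family, was at 1.17 ± 0.302 FPKM in WT and 1.03 ± 0.0315 in CTGF_KO (SD, n = 3, adjusted p = 0.785).

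Of the 12915 genes tested, 6 passed the threshold, 1 higher and 5 lower in CTGF_KO. Tead1, which encodes a DNA-binding partner of YAP, rose from 1.11 ± 0.194 to 5.99 ± 0.146 FPKM (SD, n = 3), a 5.38-fold ratio of means. Nfat5, the transcription factor of the response to hypertonic stress, fell from 11.7 ± 0.309 to 3.55 ± 0.148 FPKM (SD, n = 3). Bola1, which encodes a mitochondrial protein of iron-sulfur cluster biology, fell from 12.2 ± 1.13 to 2.09 ± 0.646 FPKM (SD, n = 3). Ctdsp2, a small C-terminal domain phosphatase gene, fell from 29.2 ± 1.8 to 11.5 ± 1.59 FPKM, Dcaf10, a substrate receptor gene of cullin ubiquitin ligases, from 9.36 ± 0.0491 to 3.68 ± 0.348, and Pyurf from 12.3 ± 0.582 to 5.97 ± 0.209 (SD, n = 3 each).

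The log2 differences and adjusted p-values from limma were 1.73 (SE 0.10, adjusted p = 0.00219) for Tead1, −1.48 (SE 0.08, adjusted p = 0.00219) for Nfat5 and −2.12 (SE 0.16, adjusted p = 0.00849) for Bola1. They were −1.15 (SE 0.09, adjusted p = 0.00849) for Dcaf10, −1.28 (SE 0.11, adjusted p = 0.0123) for Ctdsp2 and −0.93 (SE 0.08, adjusted p = 0.0123) for Pyurf. For each of the 6 genes, all 3 CTGF_KO libraries lay on one side of all 3 WT libraries. Tead1 lies on chromosome 7 (112679318 to 112906807), Nfat5 on chromosome 8 (107293470 to 107379517), Bola1 on chromosome 3 (96196588 to 96219709) and Dcaf10 on chromosome 4 (45342101 to 45379759). Ctdsp2 lies on chromosome 10 (126978717 to 126999975) and Pyurf on chromosome 6 (57686576 to 57692078). In M21, Bola1 overlaps Gm15444, Pyurf overlaps Gm26712 and Gm37397, Tead1 overlaps Gm44462, and Ctdsp2 holds the microRNA genes Mir26a-2 and Mir546, all on the same strand. The reads of these genes could thus be divided differently. For Tead1, Nfat5 and Ctdsp2, another listed transcript also had the opposite sign to the gene, with values given below. Whether the assignment of reads to transcripts enters these gene values was not tested. Leaving out any 1 WT library left only Nfat5 and Tead1 past the threshold, and the test without moderation left only Nfat5 (adjusted p = 0.0221).

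**Figure D1:**
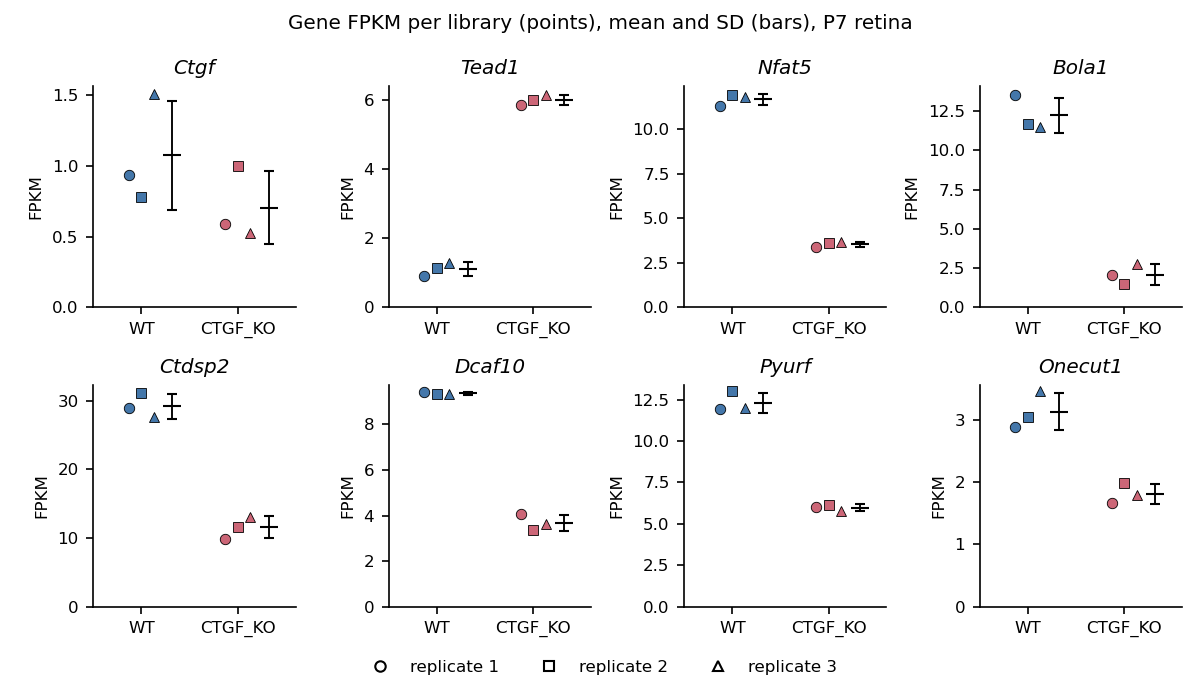
FPKM of Ctgf, of the 6 genes past the threshold and of Onecut1 in each library (points; the marker gives the replicate), with the mean and SD of 3 libraries per group (bars), on linear axes that start at 0. Tead1 stands at 5.84 to 6.13 FPKM in CTGF_KO against 0.901 to 1.28 in WT, while the Ctgf values of the groups overlap.

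At an unadjusted p under 0.05, 1204 genes differed, 495 higher and 709 lower in CTGF_KO, where chance alone gives about 646 on average. Other splits of the 6 libraries into groups of 3 gave 224 to 1108 such genes, so a count near the real one also came from another grouping. With the real groups the count was 732 without WT replicate 1, 598 without WT replicate 2 and 897 to 1428 without any other single library. In fits chosen after seeing the data it was 797 with the lens level as a covariate and 606 without WT replicate 1 and CTGF_KO replicate 3. With the 1.5-fold condition 89 genes remained, 56 higher and 33 lower. The groups did not overlap in 2386 genes, or 18.5% of those tested, where chance gives 10%. Rescaling the libraries to an equal FPKM total moved the median log2 difference of all genes from −0.02 to −0.11, and the split of the looser count from 56 higher and 33 lower to 66 higher and 190 lower. Every CTGF_KO total was above every WT total, so this rescaling lowers CTGF_KO values against WT by construction.

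Among genes that did not pass the adjusted threshold, 8 are described from those with the smallest p and non-overlapping groups. They are a choice and not the 8 smallest, so they show no theme. Ssbp3, Plk5, Coa7 and Cited1, higher in CTGF_KO, had smaller unadjusted limma p-values (0.000361 to 0.00147) than Slc17a7 (0.00155) and Nxnl1 (0.00185). Otx2, a transcription factor gene of photoreceptors and bipolar cells, was at 138 ± 3.91 FPKM in WT and 187 ± 7.7 in CTGF_KO (SD, n = 3), a log2 difference of 0.44 (SE 0.08, adjusted p = 0.533). Nxnl1, which encodes a rod-derived cone viability factor, was at 26.4 ± 4.29 and 41.8 ± 4.73 FPKM, and Slc17a7, the vesicular glutamate transporter of photoreceptors and bipolar cells, at 22.6 ± 1.3 and 30.1 ± 1.73 FPKM. Onecut1, a transcription factor gene of horizontal cells, was at 3.14 ± 0.3 and 1.81 ± 0.164 FPKM, Hmgb2, a chromatin protein of dividing cells, at 53 ± 6.57 and 36.6 ± 0.344 FPKM, and the ephrin gene Efna5 at 7.17 ± 0.576 and 4.88 ± 0.489 FPKM (SD, n = 3 each). Pex19, a peroxisome biogenesis gene, was at 22 ± 0.836 and 30.7 ± 0.203 FPKM, and Dcaf17 at 1.61 ± 0.0661 and 3.71 ± 0.685 FPKM. Adjusted p-values of these 8 genes were 0.392 for Dcaf17, 0.413 for Pex19 and 0.533 for the others.

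Photoreceptor lists stood higher in CTGF_KO. Of 25 rod genes 24 were higher, with a median log2 difference of 0.31 and 9 genes at an unadjusted p under 0.05, although 0 passed the adjusted threshold over all genes or adjusted over the list alone. Cnga1, a subunit of the rod cyclic nucleotide-gated channel, was at 11.2 ± 2.58 FPKM in WT and 18 ± 2.87 in CTGF_KO, and Tulp1 at 78.5 ± 2.63 and 102 ± 9.92 FPKM. Pde6g, a subunit of the rod phosphodiesterase, was at 98.7 ± 19.8 and 138 ± 10.4 FPKM and Rom1, the most abundant rod gene, at 362 ± 47.1 and 440 ± 22.4 FPKM (SD, n = 3 each). The rod list rose in camera (adjusted p = 1.34e-09), a call that was lost with an estimated correlation (adjusted p = 0.469). Its mean difference was 0.18 without WT replicate 2 and 0.41 without WT replicate 3, against 0.29 with all libraries (camera adjusted p = 1.5e-05 and 3.05e-16). Of 13 cone genes 9 were higher, with a median of 0.25. Opn1sw, the short-wavelength opsin, was at 59.5 ± 8.17 and 76.5 ± 6.88 FPKM, and Cnga3, the cone channel subunit, at 2.59 ± 0.363 and 3.65 ± 0.29 FPKM (SD, n = 3 each). The cone list rose in camera (adjusted p = 0.00214; adjusted p = 0.469 with an estimated correlation; adjusted p = 0.0791 without CTGF_KO replicate 1). The level of the rod list was 0.00, −0.22 and 0.22 in WT and 0.42, 0.23 and 0.24 in CTGF_KO, and the smallest two-sided p that an exact permutation of 3 against 3 libraries allows is 0.1. That permutation gave p = 0.1 for the rod and cone lists. It gave the same for TGF-beta and BMP signalling, interferon response, immediate early genes and mitochondrial transcripts. The permutation p was also 0.1 for lists that did not pass camera: YAP and TEAD targets, matrix proteases, integrins and horizontal cells. The other lists past camera had higher permutation p-values, given below.

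All 27 cell cycle genes were lower in CTGF_KO, with a median log2 difference of −0.25 and 5 genes at an unadjusted p under 0.05, and 0 past the adjusted threshold over all genes or adjusted over the list alone. Mcm3, a replication helicase subunit gene, was at 4.06 ± 0.413 FPKM in WT and 3.04 ± 0.306 in CTGF_KO. Mcm6 of the same helicase was at 7.59 ± 0.729 and 6.16 ± 0.177 FPKM, and Cdk1, the mitotic kinase gene, at 4.12 ± 0.704 and 2.98 ± 0.409 FPKM (SD, n = 3 each). The list fell in camera (adjusted p = 9.09e-05), a call that was lost with an estimated correlation (adjusted p = 0.687). The exact permutation of the list level gave p = 0.4. Its level was 0.05, 0.29 and −0.33 in WT and −0.32, −0.20 and −0.24 in CTGF_KO, so WT replicate 3 lay below all CTGF_KO libraries. Without WT replicate 2 the mean difference was −0.11 and without WT replicate 3 it was −0.42, against −0.25 with all libraries (camera adjusted p = 0.0477 and 4.94e-15).

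Of 14 endothelial markers 13 were lower in CTGF_KO, with a median log2 difference of −0.26. Kdr, a receptor for vascular endothelial growth factor that retinal neurons also express, was at 35.1 ± 3.13 FPKM in WT and 29.3 ± 1.76 in CTGF_KO, Flt1 at 0.907 ± 0.2 and 0.587 ± 0.028 FPKM, and Cd34 at 1.23 ± 0.361 and 0.784 ± 0.0883 FPKM (SD, n = 3 each). Podxl, the most abundant marker, went the other way, with 38.1 ± 1.48 and 44.1 ± 4.16 FPKM. None of the 14 passed the adjusted threshold, over all genes or adjusted over the list alone, and limma gave 2 of them an unadjusted p under 0.05. The list fell in camera (adjusted p = 0.0165, and 0.642 with an estimated correlation), and the exact permutation of its level gave p = 0.3. Its level was 0.31 in WT replicate 3 and −0.31 to −0.08 in the other 5 libraries. WT replicate 3 was also the highest library for erythroid genes (1.30 against −1.01 to 0.34), pericytes and smooth muscle (0.20 against −0.17 to −0.03) and collagens, laminins and other matrix genes (0.25 against −0.23 to −0.04). The call was lost without WT replicate 3 (−0.06, adjusted p = 0.455), without CTGF_KO replicate 1 (adjusted p = 0.153) and without CTGF_KO replicate 3 (adjusted p = 0.133). The lists of endothelial tip cells (camera adjusted p = 0.604) and of pericytes and smooth muscle (3 genes higher and 5 lower, adjusted p = 0.604) did not pass.

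Genes of TGF-beta and BMP signalling, with which connective tissue growth factor interacts, were lower in 17 of 20 cases, with a median log2 difference of −0.15. Id1, a direct BMP target, was at 15.9 ± 1.68 FPKM in WT and 11.7 ± 0.76 in CTGF_KO, Bmpr2 at 13.7 ± 0.521 and 10.7 ± 1.56 FPKM, and Tgfb2 at 20.3 ± 3.03 and 17.2 ± 0.88 FPKM (SD, n = 3 each). The log2 difference of Tgfb2 was −0.22 with all libraries and −0.29 to −0.11 leaving out 1 library. The list fell in camera (adjusted p = 0.0119; adjusted p = 0.469 with an estimated correlation), and not without WT replicate 3 (adjusted p = 0.12) or CTGF_KO replicate 1 (adjusted p = 0.156). Of 16 genes known as targets of YAP and TEAD, 12 were lower, among them Igfbp3 at 2.1 ± 0.0737 and 1.45 ± 0.183 FPKM and Rbms3 at 2.81 ± 0.548 and 1.72 ± 0.782 FPKM (SD, n = 3 each). The log2 difference of Rbms3 was −0.52 with all libraries and −0.69 to −0.26 leaving out 1 library. The level of the YAP and TEAD list was −0.10, −0.11 and −0.13 in the CTGF_KO libraries and −0.02 to 0.02 in WT. The list did not pass camera (adjusted p = 0.118), while fry, which tests a list by itself, gave an adjusted p of 0.0282. In both lists 0 members passed over all genes or adjusted over the list alone.

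Integrins and matrix genes were mostly lower without passing as lists. Of 10 integrin genes 8 were lower, and 2 passed when adjusted over the list alone, with 0 over all genes. These were Itgb1, the common beta chain of matrix receptors, at 33.4 ± 0.924 FPKM in WT and 27.5 ± 0.791 in CTGF_KO (adjusted p = 0.0389 over the list alone), and Itga4 at 1.81 ± 0.178 and 1.12 ± 0.224 FPKM (adjusted p = 0.0389; SD, n = 3 each). Itgb5 had the opposite sign, with 22.1 ± 0.888 and 25.6 ± 1.78 FPKM. Of 33 collagens, laminins and other matrix genes 24 were lower (camera adjusted p = 0.0853), such as Vcan at 2.82 ± 0.756 and 1.97 ± 0.111 FPKM, while Vtn was at 6.98 ± 0.975 and 8.68 ± 0.95 FPKM (SD, n = 3 each). The log2 difference of Vcan was −0.35 with all libraries and −0.43 to −0.19 leaving out 1 library. Of 19 matrix proteases, inhibitors and crosslinkers 15 were lower (adjusted p = 0.0562), such as Mmp16 at 3.33 ± 0.208 and 2.07 ± 0.466 FPKM. The first matrix list passed without WT replicate 1, WT replicate 2, CTGF_KO replicate 2 or CTGF_KO replicate 3 (adjusted p = 0.0054, 0.0021, 0.0148 and 0.0382), and its mean difference was 0.01 without WT replicate 3. The second passed without WT replicate 1 or CTGF_KO replicate 2 (adjusted p = 0.0276 and 0.00421). Angiogenic growth factors and receptors were lower in 18 of 31 cases (adjusted p = 0.127, and 0.0139 without CTGF_KO replicate 2), among them Aplnr at 1.57 ± 0.77 and 0.668 ± 0.159 FPKM, Ptn at 53.1 ± 0.634 and 44.4 ± 3.38 FPKM, and the ephrin gene Efnb2 at 15.5 ± 1.74 and 11.3 ± 2.51 FPKM (SD, n = 3 each). The log2 difference of Aplnr was −0.59 with all libraries and −0.35 without WT replicate 3. Igf2, chosen after its values were seen, had the largest difference in this list and the opposite sign, with 7.55 ± 4.8 and 16.9 ± 7.4 FPKM (SD, n = 3, log2 difference 1.12, adjusted p = 0.533).

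Among the other retinal cell types, 5 of 7 horizontal cell markers were lower. Onecut1 and Prox1 passed when adjusted over the list alone (adjusted p = 0.00501 and 0.0277), and 0 passed over all genes. Prox1 was at 21.2 ± 1.08 FPKM in WT and 16.7 ± 1.47 in CTGF_KO (SD, n = 3 each), and the list as a whole gave a camera adjusted p of 0.0932. Ganglion cell markers were lower in 15 of 18 cases (adjusted p = 0.163), with Slc17a6 at 10.4 ± 1.39 and 7.68 ± 1.08 FPKM and, the other way, Sncg at 90.1 ± 13.3 and 108 ± 33.6 FPKM (SD, n = 3 each). Bipolar cell markers were lower in 14 of 18 (adjusted p = 0.56), amacrine cell markers in 12 of 18 (adjusted p = 0.226), Mueller glia markers in 11 of 18 (adjusted p = 0.417) and astrocyte markers in 5 of 9 (adjusted p = 0.604). Microglia and macrophage markers were higher in 9 of 18 cases (adjusted p = 0.314), with Cd68 at 2.36 ± 0.521 and 3.73 ± 0.456 FPKM (SD, n = 3 each). Without CTGF_KO replicate 2 the horizontal, ganglion and amacrine cell lists passed as lower (adjusted p = 0.0339, 0.00243 and 0.00762). The horizontal and ganglion cell lists also passed without WT replicate 1 (adjusted p = 0.0363 and 0.0252), and the bipolar cell list without WT replicate 2 (adjusted p = 0.047). Glial reactivity (adjusted p = 0.805), actin and SRF targets (adjusted p = 0.924), hypoxia (adjusted p = 0.0821, and 0.00341 without WT replicate 1 and 0.00846 without CTGF_KO replicate 3), Wnt and Norrin signalling (adjusted p = 0.314) and cholesterol synthesis (adjusted p = 0.604) did not pass either with all libraries. Ldha, the lactate dehydrogenase gene of the hypoxia list, was at 258 ± 22.3 and 327 ± 46.2 FPKM, and Egln3 of the same list at 1.97 ± 0.323 and 1.45 ± 0.273 FPKM (SD, n = 3 each). The interferon and inflammation list rose in camera, with 9 of 10 genes higher (adjusted p = 0.0281; adjusted p = 0.469 with an estimated correlation), among them B2m at 19.4 ± 0.86 and 24.3 ± 2.41 FPKM (SD, n = 3 each). This call was lost without WT replicate 2 (adjusted p = 0.11) or CTGF_KO replicate 1 (adjusted p = 0.156).

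**Figure D2:**
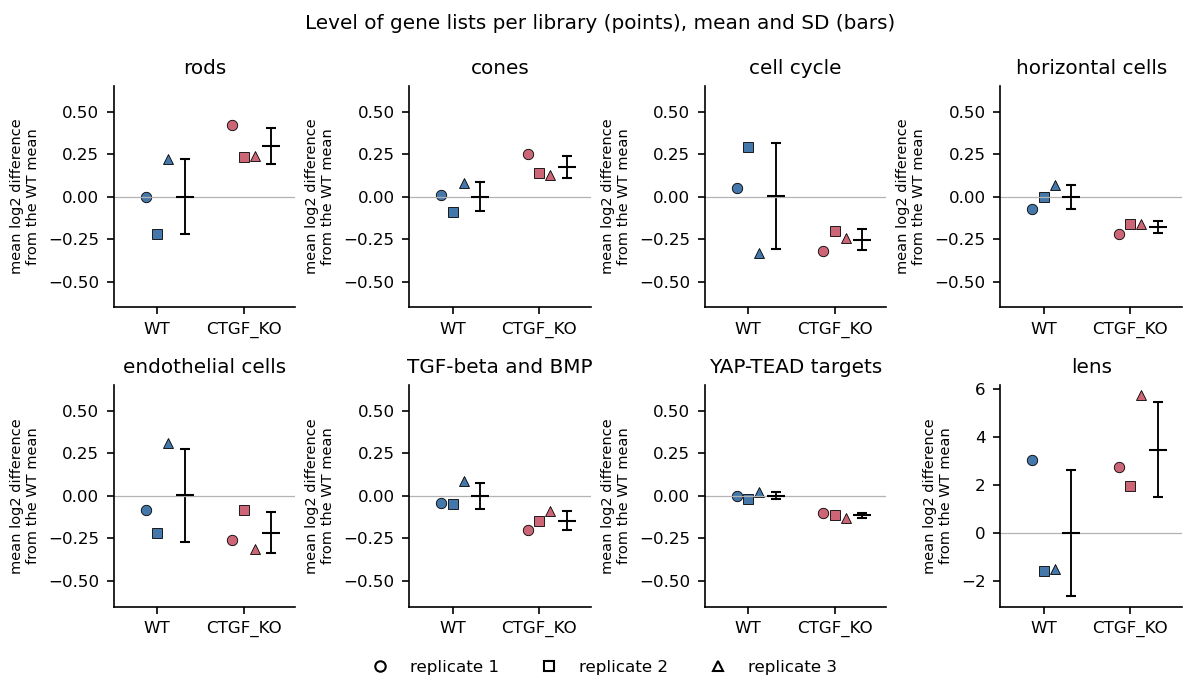
Level of 8 gene lists in each library (points; the marker gives the replicate), as the mean log2(FPKM + 1) over the list minus the WT mean, with the mean and SD of 3 libraries per group (bars); the lens panel has its own scale. The rod list lies at 0.23 to 0.42 in CTGF_KO against −0.22 to 0.22 in WT, and WT replicate 1 reaches 3.04 in the lens panel.

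Lens transcripts differed more between the libraries than any other list. All 23 lens genes had a higher mean in CTGF_KO, but WT replicate 1 carried them too: Cryaa, an alpha crystallin of the lens, was at 80.6, 0.0294 and 0.0447 FPKM in WT replicates 1 to 3 and at 82.9, 49.9 and 696 FPKM in CTGF_KO replicates 1 to 3. Lens genes made up 0.737%, 0.00359% and 0.00528% of the gene FPKM in WT and 0.49%, 0.233% and 4.08% in CTGF_KO. The list rose in camera (adjusted p = 1.47e-12, and 0.469 with an estimated correlation), and 0 of its genes passed singly. The exact permutation of the lens level gave p = 0.3. The first principal component of the genes, with 37.9% of the variance, placed WT replicates 2 and 3 at 21.9 and 21.5 and the other 4 libraries between −21.6 and −2.75. With the lens level as a covariate, chosen after seeing the data, 3 of the 6 genes passed (Nfat5, Bola1 and Tead1), and 3 of the 10 lists (rods, cones and cell cycle). Without WT replicate 1 and CTGF_KO replicate 3 together, 22 genes passed, 17 higher and 5 lower, and 4 of the 6 were among them.

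Other lists of quality or of neighbouring tissue moved less. Mitochondrially encoded transcripts were higher in 12 of 13 cases and rose in camera (adjusted p = 0.00125, and 0.469 with an estimated correlation), with mt-Co2 at 1810 ± 103 FPKM in WT and 2360 ± 501 in CTGF_KO (SD, n = 3 each). The log2 difference of mt-Co2 was 0.37 with all libraries and 0.20 to 0.48 leaving out 1 library. Under quantile normalization the mean difference of the mitochondrial list was −0.08. Immediate early genes, which respond within minutes to handling or activity, were higher in 9 of 12 cases (adjusted p = 0.00502; adjusted p = 0.487 with an estimated correlation; 0.09 against a mean of 0.17 without WT replicate 3, adjusted p = 0.148), with Egr1 at 4.42 ± 1.03 and 6.55 ± 1.01 FPKM (SD, n = 3 each). Markers of pigment epithelium and melanocytes were higher in all 10 cases (camera adjusted p = 0.0165, and 0.469 with an estimated correlation), with Dct at 4.33 ± 1.32 and 6.01 ± 0.646 FPKM. The exact permutation of their level gave p = 0.3. The camera call was lost without WT replicate 2, CTGF_KO replicate 1 or CTGF_KO replicate 3 (adjusted p = 0.0766, 0.057 and 0.133), with a mean of 0.11 without WT replicate 2 against 0.17. Erythroid genes (adjusted p = 0.604, and 0.0309 without WT replicate 2, with Hbb-bs at 109 ± 96.6 and 72 ± 26.7 FPKM, SD, n = 3 each), fibroblast genes (adjusted p = 0.942), skeletal muscle genes (adjusted p = 0.891) and replication-dependent histones (adjusted p = 0.256) did not pass, and the histone list had a median of 0.07 and a mean of −0.10, with the camera direction that of the median. Hist2h2aa1 of that list was at 28.5, 25.2 and 30.9 FPKM in WT replicates 1 to 3 and at 27.9, 0 and 0.0442 in CTGF_KO replicates 1 to 3, and it passed without CTGF_KO replicate 1 (adjusted p = 5.66e-05 in limma, and 0.533 with all libraries).

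At the transcript level 6 of 25082 transcripts passed, 3 higher and 3 lower in CTGF_KO, of which 5 are described here, and at an unadjusted p under 0.05 there were 1267, where chance gives about 1254. The 10-exon transcript ENSMUST00000100640.4 of Sqle, the squalene epoxidase gene, was at 6.34, 10.2 and 7.08 FPKM in WT and listed at 0 in CTGF_KO (adjusted p = 0.0369), and ENSMUST00000038217.13 of Dtx3 fell from 16.7 ± 3.38 to 1.86 ± 0.337 FPKM (SD, n = 3, adjusted p = 0.0369). The 6-exon transcript ENSMUST00000112191.7 of Parp11, a mono-ADP-ribosyltransferase gene, was listed at 0 in WT and at 10.2, 7.29 and 7.54 FPKM in CTGF_KO (adjusted p = 0.0309). The 4-exon transcript ENSMUST00000118268.8 of Psph, the phosphoserine phosphatase gene, was listed at 0 in WT and at 6.03, 6.92 and 5.24 FPKM in CTGF_KO (adjusted p = 0.0309), and ENSMUST00000202170.3 of Pds5b, a cohesin regulator gene, rose from 0.379 ± 0.271 to 13.3 ± 2.71 FPKM (SD, n = 3, adjusted p = 0.0369).

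None of these 5 genes passed at the gene level in limma, where their log2 differences were −0.27 to 0.12 (adjusted p 0.54 to 0.995). The other listed transcripts of the gene had the opposite sign in sum in each case, which follows where the gene level moves little, since a gene value is made of its transcripts. The 9-exon Parp11 transcript ENSMUST00000039680.6 was at 9.26 ± 1.69 FPKM in WT and 1.22 ± 0.936 in CTGF_KO, and a 7-exon one, ENSMUST00000112193.7, at 1.19 ± 0.401 and 1.73 ± 0.766 FPKM (SD, n = 3 each). The 11-exon Sqle transcript ENSMUST00000022977.13 was at 9 ± 1.9 and 18 ± 0.751 FPKM (SD, n = 3 each). The Pds5b transcript ENSMUST00000016569.10, which has 35 exons like the one that rose and a 3' UTR of 2845 against 2020 bases, was at 11.6 ± 0.734 and 2.75 ± 0.551 FPKM (SD, n = 3 each). For Tead1, the transcript ENSMUST00000069256.11, with a 3' UTR of 8148 bases, was at 0.62 ± 0.376 and 7.88 ± 0.322 FPKM (SD, n = 3, adjusted p = 0.0733). Another Tead1 transcript, ENSMUST00000106638.8, with a 3' UTR of 1333 bases, was at 1.51 ± 0.875 and 0.513 ± 0.157 FPKM (SD, n = 3, adjusted p = 0.819). For Nfat5, ENSMUST00000169453.7, with a 3' UTR of 8368 bases, was at 5.82 ± 1.09 and 0.669 ± 0.0298 FPKM (SD, n = 3, adjusted p = 0.0997). The Nfat5 transcript ENSMUST00000077440.12, with a 3' UTR of the same 8368 bases, was at 3.52 ± 1.4 and 0.773 ± 0.304 FPKM (SD, n = 3, adjusted p = 0.819), and ENSMUST00000125721.7 at 1.91 ± 0.689 and 2.3 ± 0.421 FPKM (SD, n = 3, adjusted p = 0.842). The other listed Nfat5 transcripts were ENSMUST00000075922.10 at 0.779 ± 0.0337 and 1.51 ± 0.103 FPKM and ENSMUST00000147588.1 at 0.42 ± 0.0222 and 0.735 ± 0.144 FPKM (SD, n = 3 each, adjusted p = 0.819). For Ctdsp2, ENSMUST00000105256.9 was at 33 ± 2.29 and 11.7 ± 1.41 FPKM (SD, n = 3, adjusted p = 0.0656) and ENSMUST00000105255.2 at 0.482 ± 0.344 and 1.66 ± 1.29 FPKM (SD, n = 3, adjusted p = 0.819). None of the 5 transcripts passed with any single library left out, and 0 of them passed when WT replicate 1 and CTGF_KO replicate 3 were both left out.

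**Figure D3:**
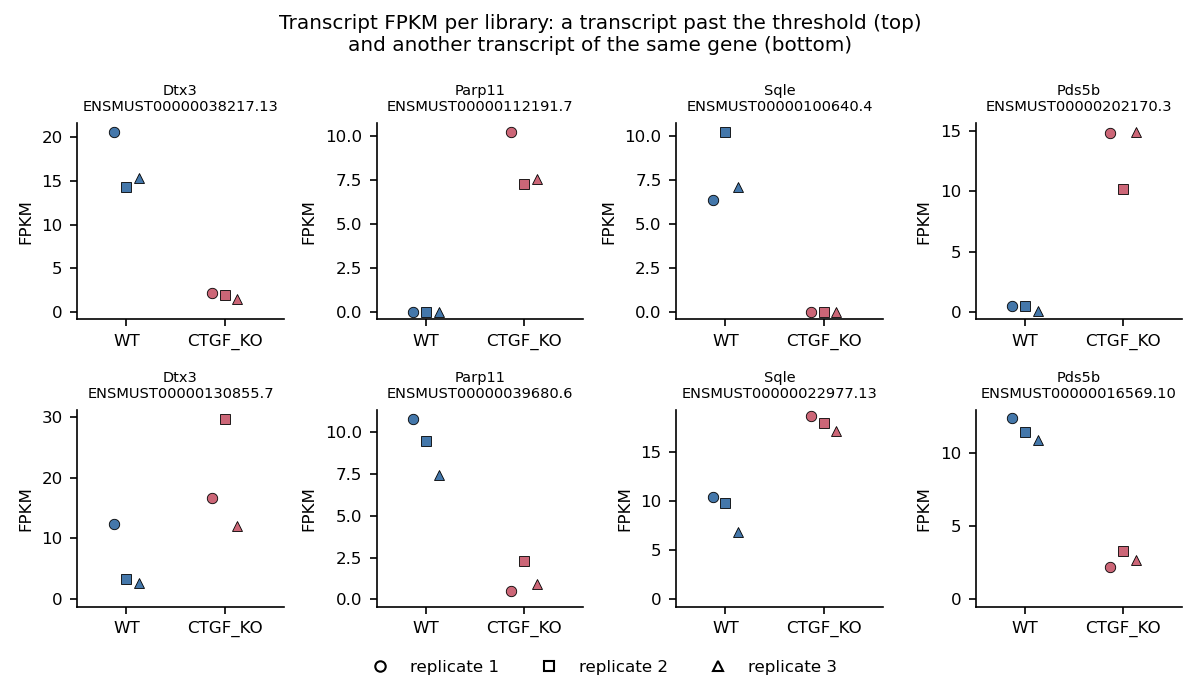
FPKM per library (points; the marker gives the replicate) of 4 transcripts past the threshold (top) and of another transcript of the same gene (bottom), WT on the left and CTGF_KO on the right of each panel, on linear axes. The upper Sqle transcript is listed at 0 in all 3 CTGF_KO libraries, and the upper Parp11 transcript in all 3 WT libraries.

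The authors' deposited table of changed genes lists 16 higher and 14 lower genes, with folds of at least 1.51 and p-values of at most 0.048, of which 1, Nfat5, has a deposited q-value under 0.05 (0.0283). In the authors' deposited table the listed genes include all 6 that passed here. Of the 30, 29 were tested in limma and all 29 had an unadjusted p under 0.05. The filter on mean FPKM left out the remaining gene. The authors' deposited table of changed transcripts lists 194 higher and 263 lower, with 5 q-values under 0.05, and 6 of them passed here. These lists were chosen on the same libraries and are not independent evidence. In the authors' deposited table Ctgf has a p-value of 0.225 and a q-value of 0.668.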

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

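The fits with a lens covariate and without WT replicate 1 and CTGF_KO replicate 3 were chosen only after the results were seen. Where no other reason is given, the cause was not tested. The 6 genes became 1 without moderation, 0 without moderation and with a library covariate, 3 with the lens covariate, 22 without both libraries and 2 to 9 leaving out 1 library. The 89 genes of the looser count became 220 and 245 with pseudocounts of 0.1 and 0.01, 256 rescaled to an equal total, 29 without moderation, 166 with library weights, 227 with the lens covariate, 164 without both libraries and 59 to 174 leaving out 1 library (59 without CTGF_KO replicate 2, 174 without CTGF_KO replicate 1). The smaller pseudocounts raise log2 differences of weakly expressed genes by construction. The 6 transcripts became 2 without moderation, 0 without moderation and with the library covariate, 1 with the lens covariate, 0 without both libraries and 1 to 7 leaving out 1 library. The 10 lists became 0 with an estimated correlation, 1 with fry and 2 with its mixed test, 3 with the lens covariate, and 5 to 16 leaving out 1 library (5 without CTGF_KO replicate 1, 16 without CTGF_KO replicate 2). The list that passed fry, targets of YAP and TEAD, was not among the 10, so fry kept 0 of them. Of the 2 lists in the mixed test, cones were among the 10 and horizontal cells were not. Of the authors' 30 genes, 6 passed the adjusted threshold and 29, all that were tested, the unadjusted one.

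Ctgf lay between −0.12 and −1.07 under 20 alternatives (adjusted p 0.22 to 1), and a filter at 1 FPKM removed it. The library covariate, fitted without moderation, had a correlation of −0.916 with the groups over the genes, so by construction it leaves little of the group difference to estimate. Under it the sign turned for Kdr (0.10), Efnb2 (0.25), Pde6g (−0.19), Rom1 (−0.14), Mcm6 (0.03), mt-Co2 (−0.18), Dct (−0.09), Ldha (−0.02), Vtn (−0.16), Foxd1 (−0.08), Sncg (−0.55) and Npy (−0.25). It also turned for the lists of interferon response (−0.06), cell cycle (0.30), endothelial tip cells (−0.30), rods (−0.12) and mitochondrial transcripts (−0.13), while the mean of the cone list went to 0.00. Of these the cell cycle list passed camera as higher and the tip cell list as lower. The histone list, whose mean was −0.10 and camera direction higher, passed camera as lower (−0.65). Of the 11 lists that passed under it, 2 were higher and 9 lower, and 3 of the 10 were among them. Elsewhere Cyr61 turned without WT replicate 3 (−0.17 to 0.02 leaving out 1 library), Hbb-bs turned without WT replicate 3 (−0.87 to 0.45 leaving out 1 library) and with the lens covariate (0.13), Sncg turned without CTGF_KO replicate 2 (−0.01 to 0.41 leaving out 1 library), Fabp7 under quantile normalization (−0.03), Ndufa4l2 with library weights (−0.09), and mitochondrial transcripts turned under quantile normalization (−0.08). Over all 130 genes that the naming rule gives, named here or not, 43 changed sign under at least 1 setting, 34 of them under the library covariate and 14 under another, and 0 of 11 transcripts did.

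Of the 23 lists that did not pass, 14 changed the sign of their mean under at least 1 setting. Without WT replicate 3 bipolar cells stood at 0.10, erythroid cells at 0.41, pericytes and collagens at 0.01 each and hypoxia at −0.02, without CTGF_KO replicate 1 ganglion cells at 0.02 and amacrine cells at 0.01, and under the library covariate integrins at 0.08 and cholesterol synthesis at 0.15. So the directions given for such lists are counts of members and not calls.

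With the replicate number as a replicate block, 2 genes, 0 transcripts and 11 lists passed. Libraries with the same number showed no shared deviation: the correlations of their deviations were 0.0129, 0.171 and −0.156 over genes. These few values cannot exclude a pairing. WT replicate 1 and CTGF_KO replicate 1 were the most similar of all pairs (Pearson r 0.987 over genes and 0.920 over transcripts). Depth is unknown for these values.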

Other observations

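The tests of genotype as the cause of the lens transcripts, of the rod and cell cycle lists and of the 6 transcripts were chosen only after the results were seen.

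Single markers of other retinal cells had values that did not pass the adjusted threshold in limma (adjusted p 0.533 to 0.679). Glul, the glutamine synthetase of Mueller glia, was at 83.7 ± 4.24 FPKM in WT and 71 ± 6 in CTGF_KO. Gfap, the intermediate filament gene of astrocytes and reactive glia, was at 4.47 ± 0.0863 and 3.66 ± 0.337 FPKM (SD, n = 3 each). Pdgfra of astrocytes was at 8.47 ± 0.737 and 6.6 ± 0.956 FPKM, and the pericyte markers Rgs5 and Zic1 at 13.1 ± 4.71 and 8.64 ± 0.85, and 5.44 ± 1.14 and 3.65 ± 0.246 FPKM. The log2 difference of Rgs5 was −0.50 with all libraries and −0.25 without WT replicate 3. Other markers of these cells went the other way: Fabp7 of astrocytes was at 286 ± 31.1 and 326 ± 10.1 FPKM, and of the pericyte list Ndufa4l2 was at 50.3 ± 11.8 and 62.5 ± 22.1 and Foxd1 at 0.497 ± 0.148 and 0.729 ± 0.269 FPKM (SD, n = 3 each). The log2 difference of Ndufa4l2 was 0.28 with all libraries and 0.01 to 0.47 leaving out 1 library. Isl1 was at 15.4 ± 4.29 and 10.5 ± 1.09 FPKM, while Cabp5 of bipolar cells was at 3.73 ± 0.435 and 4.6 ± 0.569 and Npy of the amacrine cell list at 73.3 ± 8.91 and 87.9 ± 18 FPKM. Gad1, which makes GABA in amacrine cells, was at 14.6 ± 0.866 and 12.5 ± 0.97, and Tpm4, an actin-binding tropomyosin gene, at 50 ± 1.22 and 41.4 ± 0.804 FPKM. The complement gene C1qa of microglia was at 10.4 ± 1.25 and 13.2 ± 1.82 FPKM (SD, n = 3 each). Within 20 Mb of Ctgf, 11 of 129 genes (8.53%) had an unadjusted p under 0.05 against 1193 of 12786 elsewhere (9.33%; odds ratio 0.906, 95% interval 0.439 to 1.69, two-sided Fisher's exact p = 0.879), and 0 of the 6 genes past the threshold lie there.

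Lens genes were high in WT replicate 1 and in all 3 CTGF_KO libraries and low in the other 2. Genotype as the whole cause was argued against, since 21 of 23 lens genes were higher in WT replicate 1 than in CTGF_KO replicate 2. Lens tissue carried over at dissection may be the source, and it would bring its genes in 1 ratio. Over the lens genes the lowest Pearson r between WT replicate 1 and a CTGF_KO library was 0.959. Genes are not independent replicates in that correlation. Over all genes r between the groups was 0.960 to 0.987, so a high r by itself is common between these libraries. Another source that holds the lens genes in a steady ratio would also give such a value. It cannot tell carried tissue from that source. The ratio was not equal either. Lens genes summed to 1584 FPKM in WT replicate 1 and 1066 in CTGF_KO replicate 1, but Cryaa was at 80.6 and 82.9. In the same libraries the lens genes Crygs and Mip were at 59.3 and 54.4, and 11.2 and 12.1 FPKM. Crygs was listed at 0 in WT replicates 2 and 3, and Mip was at 0 and 0.0357 FPKM there. Whether genotype adds to the amount carried over stays open.

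The rod list was higher in CTGF_KO by 0.29 (0.18 without WT replicate 2) and the cell cycle list lower by a mean of −0.25 (−0.11 without WT replicate 2 and −0.42 without WT replicate 3). Variation between retinas of either genotype along 1 axis, such as their stage of maturation, may give the same pattern: the WT libraries ranged over 1.51 times the group difference of the rod list and 2.46 times that of the cell cycle list. The spread was smaller in CTGF_KO, with an SD of 0.11 against 0.22 in WT for rods and 0.06 against 0.31 for the cell cycle. So the wide range was seen in WT only. WT replicate 2 was lowest for rods and highest for the cell cycle (−0.22 and 0.29) and WT replicate 3 the reverse within WT (0.22 and −0.33), but 3 libraries are too few to test a shared axis. With lens tissue carried over as a covariate the rod difference was 0.31 (SE 0.22) against 0.29 (SE 0.14) without and the cell cycle difference −0.28, both past camera (adjusted p = 3.08e-06 and 0.00242). These calls rest on the preset correlation. Without the covariate both were lost with an estimated correlation (camera adjusted p = 0.469 and 0.687). The covariate thus left neither difference smaller. The rod level was 0.00 in WT replicate 1 at a lens level of 3.04, and 0.23 in CTGF_KO replicate 2 at a lens level of 1.96. These libraries differ in genotype, so that pair cannot separate the lens level from genotype. Within CTGF_KO the rod levels were 0.42, 0.23 and 0.24 at lens levels of 2.74, 1.96 and 5.73 in replicates 1 to 3. Within WT the rod level of replicate 1 lay between those of replicates 2 and 3 (−0.22 and 0.22), whose lens levels were −1.56 and −1.48. Rods thus did not rise steadily with the lens level within a group. But WT replicate 1 was the only WT library with high lens genes, and the error is too wide to exclude carried lens tissue. A difference by genotype stays open as well.

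In the 6 transcripts past the threshold a change of the whole gene was argued against, since in 6 of 6 genes the 95% interval at the gene level excluded 0.5 of the transcript's log2 difference. In 6 of 6 genes the other listed transcripts moved the opposite way in sum, but a gene value is made of its transcripts, so this follows from the gene level and adds no support. Reads of the gene moved to another listed transcript by the assembly and a change of isoform by genotype stay open and cannot be told apart without the reads.

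The 6 libraries split 10 ways into groups of 3, too few for a share under 0.05. As many genes past the threshold came from 1 of the 10 splits, the real one with 6 (highest other 5), and for the looser count also from 1, with 89 (highest other 85). As many transcripts came from 8 of the 10 splits, 6 in the real one and 28 in the highest other, which set WT replicates 1 and 2 with CTGF_KO replicate 1 and also gave the 5 genes, with 1108 at an unadjusted p under 0.05 against 1204. A split that calls several times the real count points to a structure of the libraries, whose source was not tested. CTGF_KO replicate 2 stood apart at the transcript level, with 1875 transcripts listed at 0. As many lists came from 4 of the 10, 10 in the real one and 14 in the highest other.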
